A study of Mus musculus with 10 samples.

How the data were processed

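The series holds bulk RNA sequencing of CD8+ T cells from wild-type mouse spleen after 5 days of culture with 10 mM N-acetylcysteine or without it, with 10 libraries in 2 groups of 5. Groups and replicate numbers were taken from the titles and agent labels. Per the labels' protocols, libraries were made from 1.3 µg of total RNA each. Per the file headers, the deposited table holds a read count and an FPKM value for every gene and library. The authors' read counts are whole numbers with a different total in each library and were used as deposited. The authors' FPKM values equal the count divided by the gene length given in the table and by the library total, checked for counts of 50 or more, where the implied totals deviated by at most 0.0012%; they were not tested. The aligner, the counting tool and the annotation are not given in the sources used here. The submitters' processing notes name the builds GRCm38 and mm10.

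The table has 21898 genes with Ensembl identifiers and symbols, of which 21794 (99.5%) are in GENCODE M21 and 99.8% of those are protein coding. Only 511 (2.34%) have the same start and end as in that GRCm38 annotation, so the build of the table's coordinates is not settled and positions are given by chromosome only. In 22 rows a symbol is shared with another row; these carry their identifier, and the row with the most reads keeps the symbol. No measurement column was left without a sample. Immunoglobulin and T cell receptor segments were not analysed here. Totals ran from 13.3 to 17.71 M reads per library, at which 1 read is far below 1 CPM; such depth covers counting error only, and the spread between libraries sets the precision of each comparison.

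Counts were tested in R 4.3.3 with edgeR 4.0.16 by the quasi-likelihood F test (glmQLFit with robust estimation) after filterByExpr and TMM normalization, NAC against control, without a covariate. P-values were adjusted by the Benjamini-Hochberg method over the 11403 genes tested, with a threshold of 0.05, two-sided. Log2 fold changes are NAC minus control as fitted by edgeR. The standard error is the size of the log2 fold change divided by the square root of F. A prior count of 2 was used for log2 CPM values only. Fold changes carry edgeR's own smaller default prior count, so those of genes near the floor are somewhat shrunk. CPM values are TMM-normalized; means carry the SD over 5 libraries. Sums over markers of other cells use CPM with all genes kept. Fold changes within library sets come from contrasts in 1 fit with a term for each group and set, unless a fit to these libraries alone is named.

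The rule for naming genes took the 8 largest rises and 8 largest falls among called genes whose groups do not overlap and whose mean in the higher group is at least 10 CPM. It always took Tcf7, Pdcd1, Slamf6, Havcr2, Tox, Gzmb and Ifng; results of some other genes it took are not reported here. From each list it took up to 2 rising and 2 falling members with the smallest adjusted p, or the 2 most abundant tested members where none passed. It named 88 genes. The 34 lists cover T cell states, effector and cytokine genes, redox and metal genes, stress responses, metabolism, proliferation, survival, interferon and signalling genes, and markers of other cell types. The 27 lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over these lists. Camera with an estimated correlation called 0 lists at adjusted p below the threshold, while fry called 6. Fry tests a list against no change, whereas camera tests it against the other genes. The lists, this rule, the tests and the first set of alternatives were chosen before the data were examined.

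Alternatives were DESeq2 1.42.0 size factors, library size alone and upper quartile factors in the same fit, DESeq2's Wald test, limma-voom, 2 other filters on low counts, a replicate block, each library left out in turn, estimation without robustness, a test against a fold of 1.5, and library sizes without the 20 most abundant genes. A term for the library set and fits to libraries 1 and 2 or 3 to 5 alone were added after the data had been seen. The sets are those that principal component 1 of log2 CPM separates.

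Library numbers shared by the groups were checked for pairing. Deviations from the group means correlated across genes with r of 0.48 to 0.60 between libraries of the same number, 0.47 to 0.58 between other numbers of the same set, and -0.57 to -0.45 between the sets; genes are not independent replicates. Every same-number r passed 0.1, the rule for treating numbers as pairs, but only 3 of 10 libraries correlated best with their own number, so the number stands largely for the set. The main test has no term for number or set, so the difference between the sets enters its spread. The common coefficient of variation between libraries was 26.7% in that fit, 16.4% with the block and 13.1% with a set term. A gene that did not pass the main test can therefore still have changed within the sets. No 2 libraries agreed within sampling noise: the mean chi-square per gene between libraries of the same group and set was 2.38 to 4.48 for 7 pairs and 29.6 for NAC 1 and NAC 2.

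The scripts were tested on simulated data with 200 changed genes among 11403. Without a block the test recovered 48.8% of 1.5-fold, 76.7% of 2-fold and 93.3% of 4-fold changes with 0 false calls. With the block it recovered 97% of all changes with 15 false calls. Each simulated change had the same fold in both library sets, and the spread was that within group and set. In the data an interaction test gave a different effect of NAC between the sets for 41.9% of genes, so these rates may not hold there. Where reads of close paralogs could be split, values are called uncertain.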

Results

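Messenger RNA was measured by bulk RNA sequencing in CD8+ T cells isolated from mouse spleen. The cells were kept in culture for 5 days without or with 10 mM N-acetylcysteine (NAC), a thiol antioxidant that supplies cysteine for glutathione synthesis. Each group had 5 libraries, numbered 1 to 5. Reads assigned to genes came to 13.3 to 17.71 M per library, with a mean of 16.21 ± 1.70 M (SD, n = 5) in control and 15.82 ± 1.13 M (SD, n = 5) with NAC. Of the 21898 genes in the table, 11403 had enough reads to be tested. The labels do not say that the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

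The libraries of both groups fell into the same 2 sets. Libraries 1 and 2 of both groups stood apart from libraries 3 to 5 on principal component 1, which held 50.8% of the variance, and NAC and control parted on principal component 2, with 31.8%. Cd4, the co-receptor of helper T cells, was at 465 to 521 CPM (counts scaled to library size) in the 4 libraries numbered 1 and 2, and at 0.766 to 2.76 CPM in the 6 others. Cd8a, a chain of the CD8 co-receptor, was at 202 to 271 CPM in libraries 1 and 2 and at 488 to 667 CPM in libraries 3 to 5. Values within the 2 sets are therefore given for a part of the results below.

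**Figure D1:**
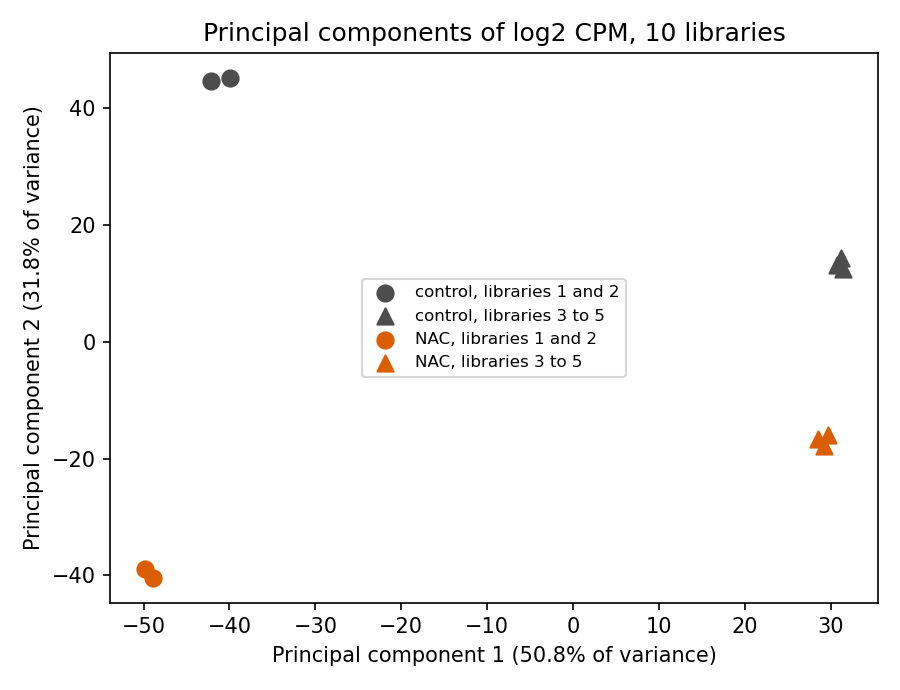
Principal components 1 and 2 of log2 CPM for the 10 libraries, one point each, with control in grey and NAC in orange, circles for libraries 1 and 2 and triangles for libraries 3 to 5. Component 1 (50.8% of the variance) parts the library numbers, and component 2 (31.8%) parts NAC from control.

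The comparison of NAC with control asks how the thiol changes CD8+ T cells in culture. The series title names the differentiation of cells positive for TCF1, the product of Tcf7, and for PD-1, the product of Pdcd1. Tcf7, a transcription factor of naive and stem-like T cells, rose from 189 ± 11.5 to 297 ± 52 CPM (SD, n = 5 per group), and Lag3, an inhibitory receptor, rose from 99.2 ± 45.1 to 222 ± 5.18 CPM. Pdcd1 was at 124 ± 32.1 CPM in control and 88.8 ± 10.5 CPM with NAC and did not pass the test. The antioxidant enzyme genes Gpx1 and Srxn1 fell 3.13-fold and 2.96-fold. The chemokine genes Ccl20, Ccl1 and Ccl3 fell 29.6-fold, 27.5-fold and 3.07-fold, and the interleukin 2 receptor gene Il2ra fell 1.57-fold. The fall of Ccl20 was mostly that of libraries 1 and 2 (log2 change -8.31, against -1.59 in libraries 3 to 5). NAC 1 and NAC 2 had only 0.0652 and 0.196 CPM of it, near the floor, so the size of that change is uncertain. Hk2, which encodes a hexokinase, fell 2.03-fold, while the glucose transporter gene Slc2a3 rose 1.92-fold.

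In edgeR's quasi-likelihood test, 1319 genes (11.6% of those tested) passed an adjusted p of 0.05, 763 higher and 556 lower with NAC. Among them 282 rose and 89 fell at least 2-fold. The NAC and control values did not overlap for 1867 of all 11403 tested genes (16.4%); chance gives a gene no overlap in 0.79% of cases. With the library number as a block, 1317 genes were higher and 937 lower, and 1212 of the 1319 genes were called again. In libraries 3 to 5 alone the common coefficient of variation between libraries was 3.6%, so small changes can pass, and this spread may be technical. There 2706 genes were higher and 2851 lower. They included 1285 of the 1319 genes, which had been selected with these libraries in the fit. Over all genes, 64.4% had the same sign of change in both library sets. Leaving out 1 library moved the total by more than 1.5 times in 6 cases: 657 genes without control 1, 631 without control 2, 824 without control 3, 866 without control 4, 857 without control 5 and 696 without NAC 2. Of the lower genes alone, 338 were left without NAC 3, 364 without NAC 4 and 321 without NAC 5.

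The 8 largest rises under the rule fixed for naming genes were in Fibcd1, H2-Eb1, Tspoap1, H2-Ob, Gsn, Spock2, Tspan9 and Adssl1. Fibcd1, which encodes a membrane receptor for acetylated sugars, was at 0.493 ± 0.326 CPM in control and 11 ± 12.4 CPM with NAC, a log2 change of 4.48 ± 0.98 (SE; adjusted p = 0.0188). H2-Eb1, a chain of the MHC class II molecule, went from 1.64 ± 0.354 to 22.5 ± 25.8 CPM (log2 change 3.77 ± 0.89 SE; adjusted p = 0.0241). H2-Ob, a chain of the class II modulator H2-O, went from 1.16 ± 0.383 to 10.2 ± 5.94 CPM (3.13 ± 0.42; adjusted p = 0.00304). Tspoap1 rose by 3.47 on the log2 scale and Gsn, the gene of the actin-severing protein gelsolin, by 2.71. Spock2 rose by 2.63, Tspan9 by 2.53 and Adssl1, a muscle-type adenylosuccinate synthase, by 2.40. The large SDs reflect the library sets: with NAC, H2-Eb1 was at 48.8 and 52.6 CPM in libraries 1 and 2 and at 3.03 to 4 CPM in libraries 3 to 5. For Fibcd1 the log2 change was 6.50 in libraries 1 and 2 and 1.59 in libraries 3 to 5, and for Tspoap1 it was 4.63 and 1. Control 1 and control 2 had only 0.283 and 0.243 CPM of Fibcd1, so the size of its change there is uncertain. Limma-voom did not call Fibcd1 (adjusted p = 0.102), H2-Eb1 (0.173), Tspoap1 (0.151) or Gsn (0.0836). The call of H2-Eb1 also ended without control 1, 2, 3 or 5 or NAC 2 (adjusted p 0.0544 to 0.0603). That of Tspoap1 ended without any control library or NAC 2 (0.0542 to 0.0631), and that of Gsn without control 3, 4 or 5 or NAC 2 (0.055 to 0.0599).

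The 8 largest falls were in Ccl20, Ccl1, Sema6d, Scin, Fsd1l, Zdbf2, Pla2g4f and Ccn1. Ccl20, the ligand of the chemokine receptor CCR6, went from 19.4 ± 22.5 to 0.634 ± 0.587 CPM (log2 change -4.89 ± 1.09 SE; adjusted p = 0.0199). Ccl1, the ligand of CCR8, went from 20.6 ± 5.37 to 0.732 ± 0.675 CPM (-4.78 ± 0.58; adjusted p = 0.00173). Sema6d, a semaphorin gene, went from 12.9 ± 2.76 to 0.501 ± 0.429 CPM (-4.66 ± 0.61; adjusted p = 0.00261). Scin, the gene of the actin-severing protein scinderin, fell by 3.27 on the log2 scale. Fsd1l fell by 2.10, Zdbf2 by 2.03, the phospholipase gene Pla2g4f by 2.01 and the matricellular protein gene Ccn1 by 1.97. Control Ccl20 was at 41.7 and 46.2 CPM in libraries 1 and 2 and at 2.63 to 3.51 CPM in libraries 3 to 5. Limma-voom did not call Ccl20 (adjusted p = 0.112), and its call ended without NAC 2 (0.0525).

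The identifiers of these genes in the table are ENSMUSG00000026841 (Fibcd1), ENSMUSG00000060586 (H2-Eb1), ENSMUSG00000034156 (Tspoap1), ENSMUSG00000041538 (H2-Ob), ENSMUSG00000026879 (Gsn), ENSMUSG00000058297 (Spock2), ENSMUSG00000030352 (Tspan9), ENSMUSG00000011148 (Adssl1), ENSMUSG00000026166 (Ccl20), ENSMUSG00000020702 (Ccl1), ENSMUSG00000027200 (Sema6d), ENSMUSG00000002565 (Scin), ENSMUSG00000054752 (Fsd1l), ENSMUSG00000027520 (Zdbf2), ENSMUSG00000046971 (Pla2g4f) and ENSMUSG00000028195 (Ccn1). Tcf7 is ENSMUSG00000000782 on chromosome 11 and Pdcd1 is ENSMUSG00000026285 on chromosome 1.

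Of the genes named in advance, Tcf7 alone passed the main test over all libraries, which counts the difference between the library sets as spread. Its log2 change was 0.65 ± 0.12 (SE; adjusted p = 0.0094), with 0.98 in libraries 1 and 2 and 0.41 in libraries 3 to 5, and all 5 NAC libraries lay above all 5 control libraries. Pdcd1 had a log2 change of -0.48 ± 0.17 (adjusted p = 0.0824), -1.02 in libraries 1 and 2 and -0.07 in libraries 3 to 5. Slamf6, a surface receptor of stem-like T cells, had a log2 change of 0.66 ± 0.58 (adjusted p = 0.484); with the block it was 0.83 (adjusted p = 0.0079), and within the sets 0.49 and 1.08. Ifng, the gene of interferon gamma, was at 136 ± 50.9 CPM in control and 87.1 ± 49.1 CPM with NAC (adjusted p = 0.382), and the block gave a log2 change of -0.82 (adjusted p = 0.0312). Granzyme B (Gzmb) was at 2380 ± 790 and 1990 ± 423 CPM (adjusted p = 0.51). By the contrasts within sets its log2 change was 0.05 in libraries 1 and 2 (adjusted p = 0.787) and -0.38 in libraries 3 to 5 (0.0196). The difference between the sets did not pass an interaction test (adjusted p = 0.0626). The inhibitory receptor gene Havcr2 was at 2.21 ± 0.588 and 1.33 ± 0.492 CPM (adjusted p = 0.156). Tox, a transcription factor of exhausted cells, was at 26.7 ± 14.5 and 29.2 ± 12.7 CPM (0.844). A term for the library set, added after the data had been seen, called Pdcd1 (-0.45, adjusted p = 0.0371).

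**Figure D2:**
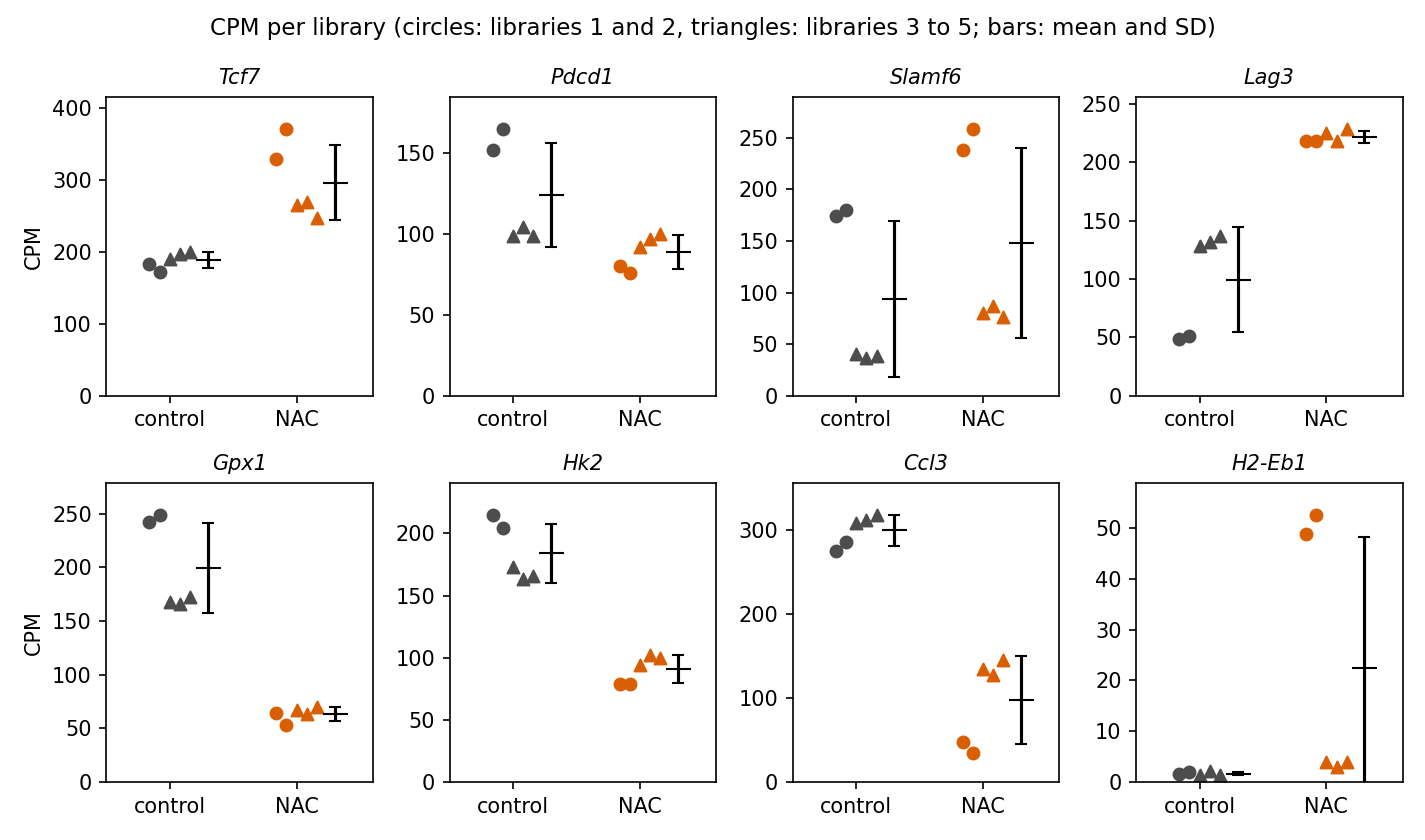
CPM of 8 genes in each library, control in grey and NAC in orange, circles for libraries 1 and 2 and triangles for libraries 3 to 5; bars give the mean and SD of the 5 libraries and are drawn from 0 upward only. Tcf7 and Lag3 are higher and Gpx1, Hk2 and Ccl3 lower in all 5 NAC libraries, while for Pdcd1 the groups differ in libraries 1 and 2 and lie close together in libraries 3 to 5.

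Among genes of stem-like and memory T cells, 3 of 20 rose, none fell and 17 did not pass. Adjusted over the list alone, 4 rose. Besides Tcf7 the named gene is S1pr1, a receptor for exit from lymphoid tissue, which rose from 8.31 ± 1.79 to 14.2 ± 1.92 CPM (log2 change 0.78 ± 0.17, adjusted p = 0.0192). The list's median log2 change was 0.23, and camera did not call it (adjusted p = 0.271). With the block 7 rose and 1 fell, and in libraries 3 to 5 alone 12 rose and 2 fell and the list was called (higher, adjusted p = 0.0107). Over all libraries fry, which tests against no change, called the list (adjusted p = 0.00416), while camera with an estimated correlation did not (0.498). Of 20 tested genes of inhibitory receptors and exhaustion, only Lag3 passed, both over all genes and adjusted over the list alone. Its log2 change was 1.16 ± 0.29 (adjusted p = 0.0289), with 2.12 in libraries 1 and 2 and 0.76 in libraries 3 to 5. Its call ended without control 2 or NAC 2, 3, 4 or 5 (adjusted p 0.05 to 0.0592). With the block 5 genes of this list rose and 1 fell. The list was not called (camera adjusted p = 0.75), except in libraries 3 to 5 alone (higher, adjusted p = 0.0394).

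Effector and cytotoxicity genes went down where they passed: 2 of 18 fell and none rose, the same count as adjusted over the list alone. Ccl3, an inflammatory chemokine, went from 300 ± 18.6 to 97.7 ± 52.5 CPM (log2 change -1.62 ± 0.36, adjusted p = 0.0199), and Gzmc, granzyme C, from 6.95 ± 3.58 to 1.11 ± 0.471 CPM (-2.64 ± 0.42, adjusted p = 0.00626). Reads of Gzmc can be shared with its close granzyme paralogs, so its value is uncertain. The list's median log2 change was -0.23 (camera adjusted p = 0.0505); the block gave 0.0221, with 5 genes lower, and 0.429 with an estimated correlation. Libraries 3 to 5 alone gave 0.000396, with 14 genes lower and 2 higher. The median was -0.24 in libraries 1 and 2 and -0.23 in libraries 3 to 5. In libraries 1 and 2 single genes went both ways, such as Klrd1 (log2 change 2.97), Klrk1 (2.41), Ccl3 (-2.78) and Ccl4 (-2.42). Leaving out 1 library also led to a call, with adjusted p = 0.017 without control 1, 0.00765 without control 2, 0.0206 without NAC 3, 0.0357 without NAC 4 and 0.0298 without NAC 5.

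Activation and interleukin 2 signalling genes were lower as a list (camera adjusted p = 0.0392; adjusted p = 0.498 with an estimated correlation). In it 3 of 20 fell and none rose, and 4 fell adjusted over the list alone and 5 with the block. Il2ra fell from 1030 ± 48.5 to 657 ± 98.9 CPM (log2 change -0.65 ± 0.11, adjusted p = 0.00693). Socs2, a feedback inhibitor of cytokine signalling, fell from 65.6 ± 27.9 to 19.4 ± 5.21 CPM (-1.76 ± 0.29, adjusted p = 0.00687). The list's median was -0.50 in libraries 1 and 2 and -0.05 in libraries 3 to 5, and its call ended without NAC 1 (adjusted p = 0.0633) or NAC 2 (0.111) and in libraries 3 to 5 alone (0.373). Of 8 tested genes of type 2 and type 17 cytokines and their regulators, 2 fell, 4 adjusted over the list alone, where 1 also rose. Il3, a growth factor for myeloid cells, fell from 10.8 ± 1.39 to 3.78 ± 0.802 CPM (-1.51 ± 0.18, adjusted p = 0.00159). Their list was not called (camera adjusted p = 0.114), with 5 lower under the block, and was called in libraries 3 to 5 alone (lower, adjusted p = 0.0311) and by fry (0.00414).

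Among tissue residency and homing genes 3 of 13 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.475). With the block 5 rose and 2 fell, and in libraries 3 to 5 alone the list was called (higher, adjusted p = 0.0407). Itgb7, an integrin chain of gut homing, rose from 119 ± 28.4 to 195 ± 8.75 CPM (adjusted p = 0.0183) and Zfp683, the residency factor Hobit, from 0.872 ± 0.288 to 2.43 ± 0.799 CPM (adjusted p = 0.0225). Itgb1, an integrin chain that binds matrix proteins, fell from 451 ± 68.8 to 302 ± 14.8 CPM (adjusted p = 0.0105), and Rgs1, a regulator of chemokine receptor signalling, from 349 ± 61.3 to 223 ± 36.2 CPM (adjusted p = 0.0197). Without control 3 the call of Zfp683 ended (adjusted p = 0.0506).

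Antioxidant genes under NRF2 control fell where they passed: 3 of 22 fell and none rose, and 5 fell adjusted over the list alone. Gpx1, a glutathione peroxidase, went from 199 ± 42.4 to 63.6 ± 6.49 CPM (log2 change -1.65 ± 0.15, adjusted p = 0.000751). Srxn1, sulfiredoxin, went from 23.4 ± 0.775 to 7.92 ± 2.51 CPM (-1.56 ± 0.19, adjusted p = 0.00156). Both were lower in each library set. The list was not called (camera adjusted p = 0.0624), and the block gave 0.044 with 6 genes lower, and 0.611 under an estimated correlation; it was also called without NAC 1 (0.00168) or NAC 2 (0.0424). Its median log2 change was 0.22 in libraries 1 and 2 and -0.26 in libraries 3 to 5, where it was called alone (lower, adjusted p = 2.12e-05). Metallothionein and metal transport genes were lower as a list (camera adjusted p = 0.017; adjusted p = 0.498 with an estimated correlation), with 3 of 7 lower and none higher, also adjusted over the list alone. It was not called in libraries 1 and 2 alone (0.0645). Mt1, the only metallothionein gene tested, was at 14.3 ± 5.32 CPM in control and 6.54 ± 6.47 CPM with NAC and did not pass (adjusted p = 0.243). Its log2 change was -0.58 in libraries 1 and 2 and -2.35 in libraries 3 to 5. Tfrc, the transferrin receptor, fell from 912 ± 252 to 561 ± 38.7 CPM (adjusted p = 0.0248). The zinc exporter gene Slc30a1 fell from 14.9 ± 1.06 to 9.91 ± 1.48 CPM (adjusted p = 0.0206). The call of Tfrc ended without control 1, control 2 or NAC 2 (adjusted p 0.0559 to 0.0579) and that of Slc30a1 without control 5 (0.0521).

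Among stress response lists only heat shock genes were called. Of 27 genes of the ATF4 amino acid response 1 passed. This was Ddit4, an inhibitor of mTOR signalling, which rose from 76.9 ± 5.82 to 113 ± 29.3 CPM (adjusted p = 0.0422). Adjusted over the list alone none passed, and the list was not called (camera adjusted p = 0.927). With the block 1 rose and 4 fell; the median was 0.47 in libraries 1 and 2 and -0.12 in libraries 3 to 5, where the list was called alone (lower, adjusted p = 0.0436). Leaving out any control library, NAC 1 or NAC 2 ended the call of Ddit4 (adjusted p 0.0681 to 0.0914). Of 19 genes of the unfolded protein response in the endoplasmic reticulum 2 rose and none fell, by either adjustment, adjusted over the list alone included (camera adjusted p = 0.91). The transcription factor gene Xbp1 rose from 127 ± 6.72 to 180 ± 6.28 CPM (adjusted p = 0.00304) and the oxidase gene Ero1b from 11.3 ± 2.53 to 17.1 ± 0.827 CPM (adjusted p = 0.0332). The call of Ero1b ended without any library other than control 5 and NAC 1 (adjusted p 0.0515 to 0.0731). Heat shock and chaperonin genes were lower as a list (camera adjusted p = 0.0303; adjusted p = 0.647 with an estimated correlation), with 3 of 10 lower and 4 adjusted over the list alone. The call of this list ended without control 1 (0.0579), control 2 (0.0529), NAC 3 (0.137), NAC 4 (0.153) or NAC 5 (0.128) and in libraries 1 and 2 alone (0.648), and fry did not call it (0.0871). Hspd1, a mitochondrial chaperonin, fell from 1700 ± 121 to 1180 ± 124 CPM (adjusted p = 0.00927) and the co-chaperone gene Dnaja1 from 342 ± 29.6 to 264 ± 20.6 CPM (adjusted p = 0.0242). Without control 1, control 2, NAC 2 or NAC 3 the call of Dnaja1 ended (adjusted p 0.0505 to 0.0622).

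Glycolysis genes moved both ways, with 3 of 19 higher and 2 lower by either adjustment, adjusted over the list alone included (camera adjusted p = 0.911). Aldoc, an aldolase, rose from 3.6 ± 0.716 to 17 ± 0.968 CPM (log2 change 2.23 ± 0.16, adjusted p = 0.000233) and Slc2a3 from 50.7 ± 3.04 to 97.3 ± 11 CPM (0.94 ± 0.09, adjusted p = 0.000751). Hk2 fell from 184 ± 23.5 to 90.7 ± 11.3 CPM (-1.02 ± 0.12, adjusted p = 0.0011) and the glucose transporter gene Slc2a1 from 83.7 ± 21.4 to 48.7 ± 4.06 CPM (-0.78 ± 0.16, adjusted p = 0.0148). The median of the list was -0.48 in libraries 1 and 2 and 0.12 in libraries 3 to 5, where it was called alone (higher, adjusted p = 0.0495). Hypoxia response genes likewise had a median of -0.38 in libraries 1 and 2 and 0.33 in libraries 3 to 5, where their list was called alone (higher, adjusted p = 0.0173). Over all libraries 2 of 15 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.982). Pdk1, a kinase that restrains pyruvate entry into mitochondria, rose from 88.2 ± 20.3 to 138 ± 5.71 CPM (adjusted p = 0.0179) and Mxi1, an antagonist of MYC, from 18.6 ± 5.61 to 31.8 ± 1.74 CPM (adjusted p = 0.0285). Adm, adrenomedullin, fell from 2.16 ± 0.925 to 0.372 ± 0.223 CPM (adjusted p = 0.0126). Without control 1 or NAC 2, 3 or 5 the call of Mxi1 ended (adjusted p 0.0527 to 0.0639).

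None of 28 oxidative phosphorylation genes passed (camera adjusted p = 0.816), nor did any of 15 genes of fatty acid oxidation and mitochondrial biogenesis (0.475) or of 19 of sterol synthesis (0.927), by either adjustment, adjusted over the list alone included. The most abundant of each, Atp5b (1990 ± 113 and 1830 ± 148 CPM), Hadha (175 ± 3.2 and 172 ± 5.82 CPM) and Srebf2 (433 ± 79.5 and 447 ± 85.2 CPM), had adjusted p-values of 0.367, 0.856 and 0.871. With the block 3 genes of fatty acid oxidation rose, and 1 gene of sterol synthesis rose and 3 fell. The oxidative phosphorylation list had medians of 0.20 in libraries 1 and 2 and -0.18 in libraries 3 to 5. In libraries 3 to 5 alone 19 of its 28 genes fell and it was called (lower, adjusted p = 0.000357), as it was without NAC 1 (0.0376). The second most abundant of the first 2 lists were Atp5a1 (0.562) and Acadl (0.147). Of 12 genes encoded by the mitochondrial genome 1 fell, mt-Cytb, the cytochrome b gene, from 3400 ± 348 to 2320 ± 449 CPM (adjusted p = 0.0304). In all, 3 fell and 2 rose adjusted over the list alone, 3 fell with the block, and the list was not called (camera adjusted p = 0.475). The call of mt-Cytb ended without control 1, 2 or 5 or NAC 2 (adjusted p 0.0552 to 0.0721).

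Ribosome biogenesis genes were lower with NAC. Of 20, 9 fell and none rose, 19 fell adjusted over the list alone, and 12 fell with the block. Their median log2 change was -0.46, with -0.69 in libraries 1 and 2 and -0.31 in libraries 3 to 5 (camera adjusted p = 3.95e-09; adjusted p = 0.498 with an estimated correlation). Polr1a and Polr1b, subunits of RNA polymerase I, fell from 214 ± 23.7 to 148 ± 15.2 CPM (adjusted p = 0.0128) and from 164 ± 22.8 to 104 ± 15.4 CPM (adjusted p = 0.0129). Cell cycle genes were also lower as a list (camera adjusted p = 0.0029; adjusted p = 0.647 with an estimated correlation), with 4 of 28 lower, 5 adjusted over the list alone, and a median of -0.14. It was not called in libraries 1 and 2 alone (0.657) or by fry (0.067). Tyms, thymidylate synthase, fell from 119 ± 8.7 to 68.8 ± 4.53 CPM (log2 change -0.79 ± 0.08, adjusted p = 0.000751), and Ccne2, cyclin E2, from 51.1 ± 7.29 to 22.9 ± 2.53 CPM (-1.16 ± 0.12, adjusted p = 0.000751).

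Of 17 targets of p53, 2 rose and 1 fell, with 3 and 1 adjusted over the list alone (camera adjusted p = 0.822) and 3 and 2 with the block. Trp53inp1, a stress-induced nuclear protein, rose from 84.6 ± 6.73 to 184 ± 38.6 CPM (adjusted p = 0.0023) and Sesn1, a sestrin, from 27.6 ± 3.46 to 51 ± 8.41 CPM (adjusted p = 0.00466). The nuclease gene Aen fell from 128 ± 15.7 to 101 ± 5.63 CPM (adjusted p = 0.0409). In the BCL2 family 1 of 11 rose and 1 fell, 2 and 1 adjusted over the list alone (camera adjusted p = 0.747). Bmf, a promoter of apoptosis, went from 3.24 ± 1.3 to 7.43 ± 1.63 CPM (adjusted p = 0.0289) and Bcl2l1, which opposes it, from 302 ± 11.3 to 223 ± 14.7 CPM (adjusted p = 0.00698). Of 19 interferon-stimulated genes 1 rose and none fell, by either adjustment, adjusted over the list alone included (camera adjusted p = 0.927). With the block 1 rose and 3 fell, and in libraries 3 to 5 alone the list was called (lower, adjusted p = 0.0448). The only gene of 22 of the PI3K, AKT and mTOR list to pass was Pik3cd, a PI3K catalytic subunit, from 418 ± 62.2 to 555 ± 41.8 CPM (adjusted p = 0.0412); none passed adjusted over the list alone, and 2 rose with the block (camera adjusted p = 0.475). Several of these calls ended when 1 library was left out: Aen without any library but control 5 (adjusted p 0.0509 to 0.0982), Bmf without control 1 or 2 or NAC 2, 4 or 5 (0.0525 to 0.0676). The call of Pik3cd ended without any library but control 3 and NAC 1 (0.0539 to 0.0925).

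**Figure D3:**
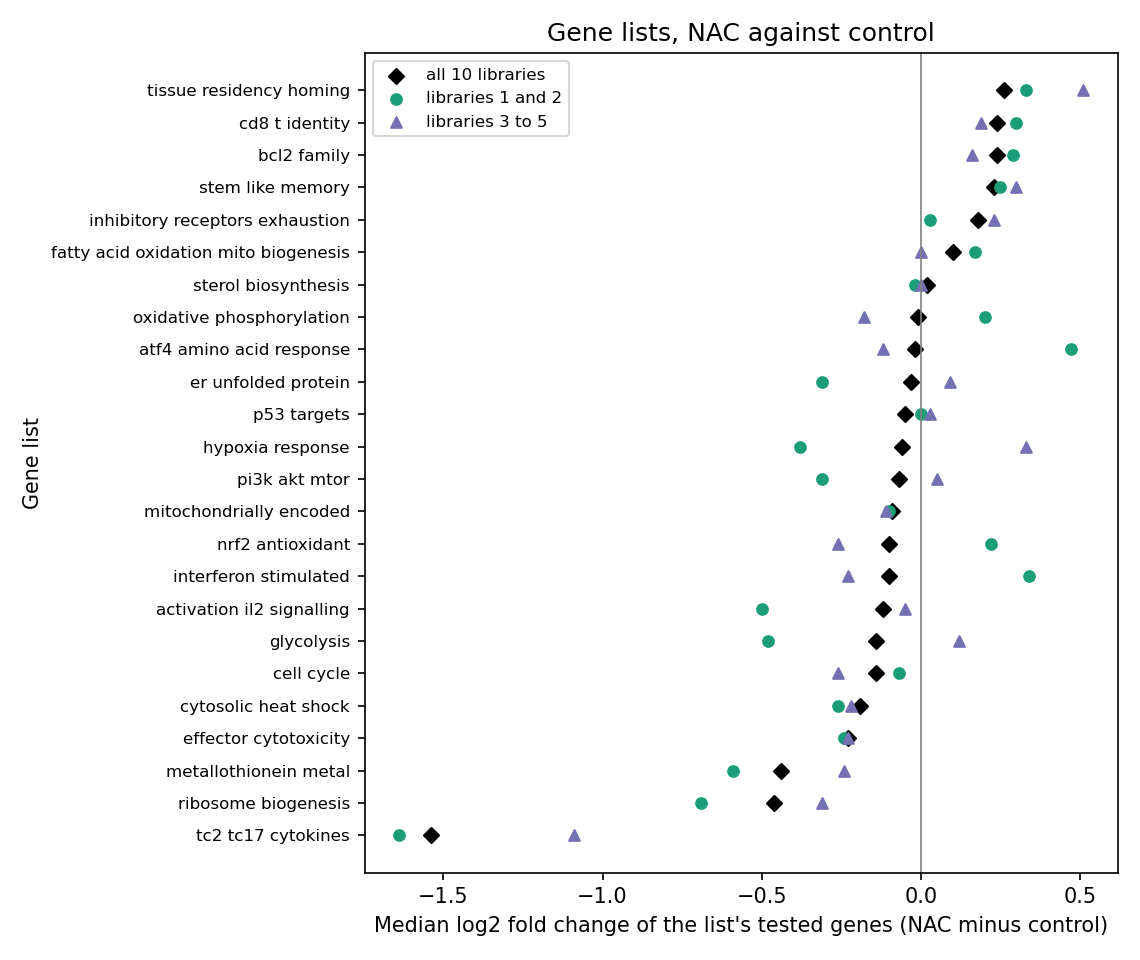
Median log2 fold change (NAC minus control) of the tested genes of 24 lists over all 10 libraries (diamonds), in libraries 1 and 2 (circles) and in libraries 3 to 5 (triangles). Ribosome biogenesis genes have medians of -0.69 and -0.31 in the 2 sets, while glycolysis and hypoxia response genes have medians on opposite sides of 0.

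Genes of T cell and CD8 identity moved both ways: 3 of 15 rose and 1 fell, 6 and 2 adjusted over the list alone, and 8 and 2 with the block (camera adjusted p = 0.209, fry 0.00414). Cd3e, a chain of the T cell receptor complex, rose from 124 ± 14.7 to 178 ± 13.2 CPM (adjusted p = 0.0108) and the costimulatory receptor gene Cd28 from 206 ± 24.8 to 304 ± 49.4 CPM (adjusted p = 0.021). Cd5, which dampens receptor signalling, fell from 500 ± 91.5 to 344 ± 38.5 CPM (adjusted p = 0.0275). Without control 3 the call of Cd28 ended (adjusted p = 0.0533), and that of Cd5 ended without control 1 or 2 or any NAC library but NAC 1 (0.0532 to 0.068). Cd4 was at 187 ± 254 CPM in control and 203 ± 275 CPM with NAC (adjusted p = 0.973), the spread being that between the library sets. None of the 7 CD4+ T cell markers passed, by either adjustment, adjusted over the list alone included (camera adjusted p = 0.806). With the block 3 rose, and in libraries 3 to 5 alone the list was called (higher, adjusted p = 0.0407). There Cd4 was at 1.35 CPM in control and 2.53 CPM with NAC, and Cd40lg and Foxp3 stayed near 1 CPM. The larger rises in CPM were in Trat1 (49.7 to 80.8), Ikzf2 (29.4 to 41.7) and Zbtb7b (18.1 to 28.1). Trat1 and Ikzf2 had higher means there than in libraries 1 and 2, so the call does not show more CD4+ T cells. Trat1, a T cell adaptor on that list, was at 41.1 ± 12 and 67.7 ± 18.9 CPM (adjusted p = 0.0783), and the block gave 0.00261.

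**Figure D4:**
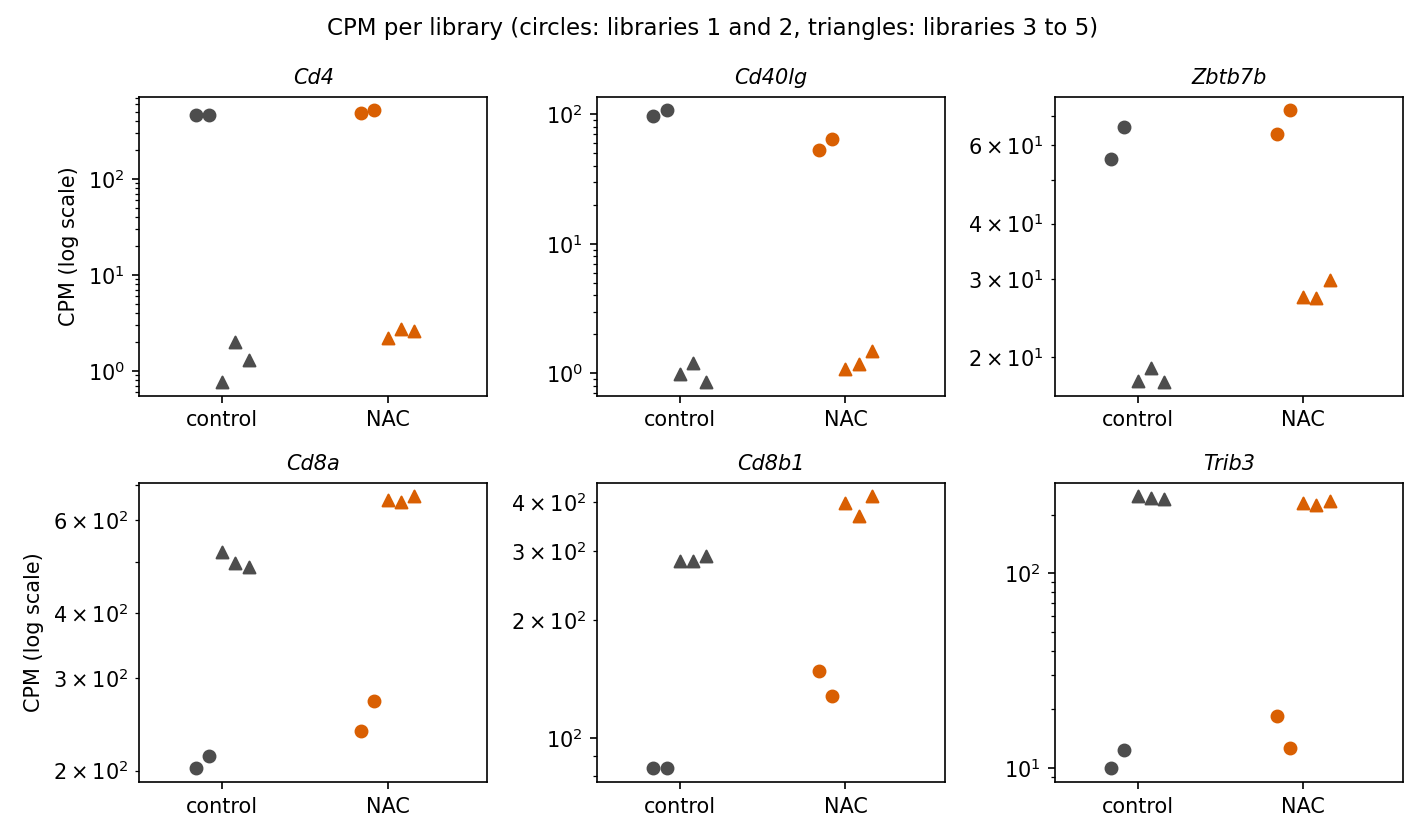
CPM on a log axis of 6 genes in each library, control in grey and NAC in orange, circles for libraries 1 and 2 and triangles for libraries 3 to 5. Cd4 is at 465 to 521 CPM in libraries 1 and 2 and at 0.766 to 2.76 CPM in libraries 3 to 5 of both groups.

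Markers of other cells were low, and few had enough reads to test. The 10 B cell markers in the table summed to 6.52 CPM in control and 13.5 CPM with NAC; of 2 tested, none passed, and 1 rose adjusted over the list alone. The B cell receptor gene Cd79b was at 4.66 ± 2.69 and 10.7 ± 1.1 CPM (adjusted p = 0.0596, 0.0239 with the block, 0.0443 without control 5), and its partner Cd79a at 0.702 ± 0.37 and 1.01 ± 0.44 CPM (adjusted p = 0.448). Markers of antigen-presenting cells had 2 of 6 higher and 1 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.849) and 2 lower with the block. With H2-Eb1, the class II gene H2-Ab1 rose from 2.42 ± 0.522 to 8.65 ± 5.48 CPM (adjusted p = 0.0226). Cd74, the invariant chain of class II molecules, fell from 84.2 ± 16.4 to 42.5 ± 3.98 CPM (log2 change -0.99 ± 0.14, adjusted p = 0.00324). The call of H2-Ab1 ended without control 1 or 5 or NAC 2 (adjusted p 0.0506 to 0.0534), and that of H2-Eb1 as given above.

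The summed markers of macrophages and monocytes were at 12.2 CPM in control and 13 CPM with NAC, nearly all of it Cd68 (11.1 ± 4.7 and 12.1 ± 1.5 CPM; adjusted p = 0.793). Neutrophil markers summed to 0.107 and 0.175 CPM, with none tested. Natural killer cell markers summed to 11.2 and 5.83 CPM with none of 3 passing, by either adjustment, adjusted over the list alone included (camera adjusted p = 0.849). In libraries 3 to 5 alone their list was called (lower, adjusted p = 0.00914). Klra7, an inhibitory receptor gene with close paralogs and thus an uncertain value, was at 7.58 ± 6.9 and 3.41 ± 3.11 CPM (adjusted p = 0.609, 0.015 with the block), and Fcer1g at 1.68 ± 1.25 and 1.02 ± 0.462 CPM (0.5). Erythroid markers summed to 4.59 and 4.71 CPM, with Car2 (adjusted p = 0.602) and Epor (0.691) tested. Platelet markers summed to 4.83 and 6.28 CPM, with Itga2b (0.448) and Gp1ba (0.12, 0.0483 with the block) tested. Mast cell and basophil markers summed to 4.36 and 4.42 CPM, with Kit tested (0.456). Stroma and endothelium markers summed to 50.2 and 90.6 CPM, nearly all from Pecam1, an adhesion molecule that T cells also express, at 50 ± 17.9 and 88.6 ± 25.1 CPM (adjusted p = 0.0761, 0.00206 with the block); it rose adjusted over the list alone.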

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

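The tests of explanations for the 3 patterns weighed here, and the interaction tests between library sets, were chosen after the results had been seen; the count of other splits was planned, but the outcome it would need was written down only afterwards.

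Other ways of splitting the libraries were fitted first. Of 100 splits of the 10 libraries into 5 and 5, only 1, the real one, gave as many as 1319 genes. The 100 were a random part of all such splits. This argues against a random grouping of single libraries. It does not exclude chance differences between cultures, since the libraries form 2 sets and those of a group may be technical repeats. The highest of the other splits gave 747 genes and put all 4 libraries numbered 1 and 2 in the same group, which points to the structure of the samples. With the set as a term, 2287 genes were higher and 1868 lower. Among the 16 splits that part every same-number pair, the real one gave 1319 genes and the highest other 0, but 16 splits are too few for a share under 0.05. For lists, 59 of the 100 splits gave at least the 5 lists of the real split, with up to 11, and 9 of the 16 paired splits did, with up to 8, so chance is not excluded for the list calls.

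Libraries 1 and 2 of both groups stand apart from libraries 3 to 5. Sequencing depth is argued against, since 3 of the 4 totals of libraries 1 and 2 lie within the range of libraries 3 to 5. CD4+ T cells in libraries 1 and 2 are a candidate explanation for part of the pattern: the lowest Cd4 value there is 465 CPM and the highest in libraries 3 to 5 is 2.76, Cd8a and Cd8b1 are lower there, and 4 of 7 CD4+ markers (Cd4, Zbtb7b, Cd40lg, Tnfrsf25) are higher in each of these libraries, though Ikzf2 is lower in each and a selection for CD8+ cells would remove such cells. Dilution of CD8+ T cell RNA as the whole cause is argued against, since 24 genes are higher in every library 3 to 5 by more than 2 times the 3.06-fold difference of Cd8b1. A difference in culture or cell state between the sets stays open, and the labels name no batch.

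The effect of NAC differed between the sets for 4778 genes (41.9%) by an interaction test, with opposite signs in 2274 of them. The choice of TMM is argued against as the cause by the alternatives tried, with 4675 genes using library size alone and 4786 using DESeq2 size factors. Upper quartile factors were not tried for this test. Fold changes correlated across genes between the sets with r of 0.54, and 0.88 among called genes, which were selected over both sets and of which 85.7% had the larger fold in libraries 1 and 2. A lower share of CD4+ T cells with NAC in libraries 1 and 2 stays open: the 4 markers above had a median log2 change of 0.13 there but went both ways (Cd40lg -0.81, Cd4 0.11, Zbtb7b 0.16, Tnfrsf25 0.48), while Cd8a and Cd8b1 were higher by 0.30 and 0.71 and effector genes also went both ways (Klrd1 2.97, Klrk1 2.41, Ccl3 -2.78, Ccl4 -2.42). A different response of differently composed or activated cultures stays open too.

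MHC class II genes were higher with NAC: 7 of 8 in the table's H2-A, H2-E, H2-DM and H2-O families rose, a group chosen after its values were seen, while H2-Aa did not pass (log2 change 1.26 ± 0.58, adjusted p = 0.171). A contribution of B cells or antigen-presenting cells in the NAC libraries stays open. Cd74, which such cells express abundantly, changed by -0.99 on the log2 scale. It cannot decide, since it was at 84.2 CPM in control, where H2-Eb1 was at 1.64 CPM, and its fall could hide a small share of such cells. Ms4a1 and Itgax stayed below 1 CPM. The B cell markers summed to 6.52 CPM in control and 13.5 CPM with NAC. Cd79b was higher with the block and in each set (log2 change 2.26 in libraries 1 and 2 and 0.80 in libraries 3 to 5). Libraries 1 and 2 as the only source are argued against for the 7 genes, which were picked over all libraries but passed in libraries 3 to 5 with p adjusted over all genes (H2-Ob 2.08, adjusted p = 2.33e-05; H2-Oa 1.93, 1.96e-05; H2-DMa 0.79, 0.000142), while H2-Aa had a log2 change of -0.34 there and 2.46 in libraries 1 and 2. The transactivator gene Ciita was at 0.484 CPM in control and 0.26 CPM with NAC. All 8 genes lie on chromosome 17 and Cd74 on chromosome 18. Their shared location follows from choosing class II genes and is no evidence of a local change in this gene cluster, which was not tested.

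Interaction tests also singled out genes named for size or in advance for which a fold could be fitted in each set (differences are the log2 effect of NAC in libraries 3 to 5 minus that in libraries 1 and 2). Among the large rises the differences were -4.91 for Fibcd1 (adjusted p = 5.38e-05), -3.70 for H2-Eb1 (4.55e-06), -3.63 for Tspoap1 (8.82e-07), -2.28 for H2-Ob (0.000485), -1.10 for Gsn (0.00529), -1.72 for Spock2 (0.00385), -1.40 for Tspan9 (0.00385) and -2.06 for Adssl1 (0.000101). Among the large falls they were 6.72 for Ccl20 (7.85e-06), 2.77 for Scin (0.000685), 0.90 for Fsd1l (0.00772), 1.53 for Zdbf2 (0.00479), 2.28 for Pla2g4f (1.89e-05) and 1.82 for Ccn1 (0.000578). Ccl1 and Sema6d had 3 or fewer reads in NAC libraries 1 and 2 together and get no difference. Ccl20 was close to that limit, at 0.0652 and 0.196 CPM there, and Fibcd1 was at 0.283 and 0.243 CPM in control 1 and 2. The sizes of their differences are therefore uncertain. Among genes named in advance they were -0.57 for Tcf7 (0.000626), 0.96 for Pdcd1 (1.46e-05) and 0.59 for Slamf6 (0.000758). Of the 64 other named genes, 37 passed this test, 3 of them with opposite signs in the sets.

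Lists also differed between the sets by camera on the interaction, none of them with an estimated correlation (adjusted p 0.221 to 0.734). The median difference was 0.38 for activation and interleukin 2 signalling (adjusted p = 0.00756), -0.40 for NRF2 antioxidant genes (0.0387), -0.44 for the ATF4 response (0.00756), 0.28 for the unfolded protein response (0.00756) and 0.48 for glycolysis (3.32e-05). It was 0.52 for hypoxia response (0.00756), -0.38 for oxidative phosphorylation (0.00246), -0.26 for cell cycle (0.00756) and 0.42 for ribosome biogenesis (0.00246).

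Single libraries lay far from the others of their group in 7 of 178 groups of values, by Dixon's criterion for 5 values (0.71), which flags about 1 in 20 groups by chance. Control 5 had 0.367 CPM of Zfp683 against 0.919 to 1.07 in the other controls, and 16.8 CPM of Slc30a1 against 14.2 to 14.6. NAC 1 had 7.37 CPM of Slc30a1 against 10.1 to 11.2, 301 CPM of Dnaja1 against 252 to 259, 2100 CPM of Atp5b against 1750 to 1800 and 480 CPM of Pik3cd against 569 to 576. NAC 2 had 962 CPM of Hspd1 against 1190 to 1280.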

How the results depend on the processing

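The library set term and the fits to part of the libraries were chosen after the data had been seen. None of the 1319 called genes tested under any alternative changed sign, though every fit shares libraries with the one that selected them. Of the 62 named calls, 42 held whichever library was left out. Against 763 genes higher and 556 lower, upper quartile factors gave 350 lower and a mean of at least 10 CPM gave 344 lower, the latter with fewer genes tested. DESeq2's Wald test gave 1243 and 1044, the replicate block 1317 and 937, and the test against a fold of 1.5, stricter by construction, 32 and 23. The library set term gave 2287 and 1868, libraries 3 to 5 alone 2706 and 2851, and libraries 1 and 2 alone 2776 and 2363. Leaving out 1 library gave 412 to 725 higher and 213 to 680 lower, with fewer samples. The share of calls that were higher was 57.8% with TMM, 69% with library size alone and 74.9% with upper quartile factors, which shifted the median log2 change of all genes from 0.012 to 0.082. Size factors, limma-voom, estimation without robustness and no filter on low counts stayed within 1.5 times of both counts. The cause was not tested for the other shifts.

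Against 5 lists lower and none higher, the estimated correlation gave 0 lower and fry gave 2 higher (stem-like and CD8 identity genes) and 4 lower, losing cell cycle (0.067) and heat shock genes (0.0871) and adding type 2 and type 17 cytokines (0.00414). Libraries 3 to 5 alone gave 6 higher (stem-like, inhibitory receptor, residency, glycolysis, hypoxia and CD4+ marker genes) and 11 lower, and libraries 1 and 2 alone 2 lower. In libraries 3 to 5 alone, 4 uncalled lists changed direction and passed: the ATF4 response (lower, adjusted p = 0.0436), glycolysis (higher, 0.0495), hypoxia response (higher, 0.0173) and interferon-stimulated genes (lower, 0.0448); the cause was not tested. With libraries left out in turn 5 or 6 lists were lower and 0 higher.

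The replicate block ended none of the 62 named calls and added Slamf6, Ifng, Cd79b, Klra7, Trat1, Gp1ba and Pecam1 and the effector and NRF2 lists; it changed no other call of a named gene or list. Over all alternatives, named genes kept direction and call in 1848 comparisons, lost the call in 157, gained it in 49, and changed sign without a call in 32. Library sizes without the 20 most abundant genes gave the same values throughout, since TMM offsets the change, so this says nothing about stability. Alternatives planned for a table of normalized values alone were not run, as counts were deposited. Depth limits genes near the floor, such as Ciita and most markers of other cells, where differences were not detectable.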

Other observations

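Apart from NAC, genes of several lists differed between libraries 1 and 2 and libraries 3 to 5. These are values of 4 and 6 libraries, not of study groups, and the sets were drawn from the same data, so no test is given. Of all 11403 tested genes, 1579 were higher in every library 3 to 5 than in any library 1 or 2 and 1391 were lower, 26% together. Of 27 genes of the ATF4 amino acid response, 23 were higher in every library 3 to 5 than in any library 1 or 2, and 1 was lower, with a median log2 difference of 1.53. Trib3, a stress-induced pseudokinase, was at 9.95 to 18.4 CPM in libraries 1 and 2 and at 224 to 248 CPM in libraries 3 to 5. The glutathione-degrading enzyme gene Chac1 was at 3.94 to 5.26 and 32 to 37.4 CPM, the cystine transporter gene Slc7a11 at 1.3 to 2.26 and 11.7 to 19.8 CPM, and the arginine and lysine transporter gene Slc7a3 at 6.49 to 23.4 and 120 to 130 CPM. Asparagine synthetase (Asns) in libraries 1 and 2 was at 73.2 CPM in control and 230 CPM with NAC, and in libraries 3 to 5 at 462 and 412 CPM.

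Sterol synthesis genes ran the other way, with 15 of 19 lower in every library 3 to 5 and none higher, and a median log2 difference of -0.62. Lss, lanosterol synthase, was at 90.6 to 97.1 CPM in libraries 1 and 2 and at 47.7 to 53.3 CPM in libraries 3 to 5. Of 18 effector genes, 10 were higher in every library 3 to 5 and none lower. Among them Klrk1, the activating receptor NKG2D, in libraries 1 and 2 was at 14 CPM in control and 74.3 CPM with NAC, against 284 and 290 CPM in libraries 3 to 5, and Klrd1, the receptor chain CD94, at 3.23 and 25.2 against 93.6 and 117 CPM. Of 19 interferon-stimulated genes, 10 were higher in every library 3 to 5 and 1 was lower, Ifih1, a sensor of double-stranded RNA, at 51.2 to 133 CPM in libraries 1 and 2 and 18.2 to 36.2 CPM in libraries 3 to 5. None of the 20 ribosome biogenesis genes parted the sets in this way. The genes named here were chosen after their values were seen.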
